A study of Mus musculus with 10 samples.

How the data were processed

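RNA was measured by sequencing in 10 libraries from B16-F1 mouse melanoma cells, 5 of the wild type and 5 of a derivative labelled ΔFOXC2, which the design text describes as lacking the transcription factor FOXC2. Per the labels' protocols, 1000000 cells were seeded in RPMI-1640 with 10% fetal bovine serum and lysed after 24 h at about 90% confluence, at passages 5 to 10. Per the same protocols, poly(A) RNA was selected on oligo(dT) beads, strand-specific libraries were made with a dUTP kit, and both ends were read for 150 cycles on an Illumina HiSeq instrument. The protocols speak of replicate experiments, and the labels do not say whether the ΔFOXC2 cells came from 1 clone or several. The p-values therefore measure the spread between cultures of these 2 lines of cells, and a difference between the lines with another origin than the targeted gene is included in every comparison.

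The deposited table holds FPKM, the fragments mapped to a gene scaled by the length of its transcript and by all fragments mapped in the library, which the authors computed. Per the submitters' processing notes, the tools were FastQC, cutadapt, HISAT2 and StringTie with build GRCm38, without versions. Read from the values, the table keeps protein-coding genes for which at least 1 group had a mean of about 0.5 FPKM or more. It holds 10735 genes, of which 7 symbols have 2 entries. Foxc2 was not analysed here. Genes the authors left out at low expression cannot be counted as changed or unchanged. FPKM divides by the fragments mapped in each library, so a large change in a few abundant genes shifts all others; the 20 most abundant genes held 9.54% to 10.5% of the FPKM sum of a library. The sum of FPKM was 240441 to 251273 per library and the median 7.84 to 8.14. Read counts were not used here and the depth is unknown: low values shared no common step between libraries, since at most 7 of 626 low genes had the same ratio in any pair. An exact 0 can be a failed assignment of reads. Eif3j2, a near copy of Eif3j1, was listed at 0 in 4 libraries and at 25.4 to 28.6 FPKM in the other 6, and was chosen as an example after its values were seen. For genes listed at 0 in some libraries, single values are therefore given in place of a mean.

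Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(FPKM + 0.1), without covariates, over the 10570 genes with a mean of at least 0.5 FPKM over the 10 libraries. The other 165 genes fell below that filter. All log2 differences are wild type minus ΔFOXC2 on this scale, which understates the change of genes with low values, and the ΔFOXC2 cells are the reference as in the design text. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05 and a fold of at least 1.5 in either direction, and only called genes are said to have risen or fallen in the wild type. The design text gives 1.5-fold and a p of at most 0.05 and does not say whether p was adjusted, so calls with the unadjusted p are given too. Printed adjusted p-values are from limma unless camera or fry is named.

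Before the data were examined, 50 gene lists were fixed for the biology of melanoma, interferon, drug response, stress, adhesion and other cell types; 47 had at least 3 tested members. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 47 lists. Camera with an estimated correlation and fry were run as alternatives; fry tests whether the genes of a list move on balance in one direction, and does not compare them with other genes. Genes were named by a rule fixed at the same time. It took the 10 called genes with the largest fold in each direction among those with at least 2 FPKM in the higher group, groups that do not overlap and an established symbol. It also took up to 2 called members per direction of each list, or its 2 most abundant members where fewer were called. Fixed by name were, among others, Foxc1, Mitf, Cd274, Vim, Cdh1, Cdh2, Mki67, Gapdh and Actb. Cdh1 was not analysed here, and some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen. Shares of FPKM per chromosome are given without a test, since the chromosomes were chosen after their shift was seen. Coordinates are those of the deposited table, in GRCm38. For GC content and length, the GENCODE annotation of GRCm38 gave values for 10555 of the 10570 genes.

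The fit was tested on simulated data with the means and spreads of the 10570 genes and 200 changed genes: it recovered 88.1% of those changed 1.75-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, with 1 unchanged gene called. With no gene changed it called 0 genes and 0 lists. The simulated genes were drawn independently of one another and in a single draw. The lists called there therefore do not show how often a list of correlated genes is called falsely. In a simulation that shifted the interferon list alone, 2 lists were called, the interferon list included. Alternatives covered the pseudocount, the filter, 2 rescalings, the variance model, library weights, the replicate number as a block, both thresholds, the list test and each library left out. Leaving out or centring chromosome 1, chromosome 8 and the distal part of chromosome 2 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.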

Results

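Gene expression was compared between wild-type B16-F1 cells, a mouse melanoma line, and B16-F1ΔFOXC2 cells, a derivative labelled as lacking the forkhead transcription factor FOXC2, to find which genes are induced or repressed where FOXC2 is present. There were 5 libraries per group, and 10570 protein-coding genes were tested. The sum of FPKM per library ranged from 240441 to 251273. The first principal component held 53.5% of the variance and separated the 2 groups. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.982 to 0.986 within groups and 0.954 to 0.965 between them.

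The targeted gene, Foxc2, was not analysed here, so the labels could not be checked against it and the genotypes stand as given. Its closest relative Foxc1 had 6.35 ± 0.330 FPKM (SD, n = 5) in the wild type and 6.20 ± 0.410 in ΔFOXC2 cells, a difference smaller than the spread between libraries (limma adjusted p = 0.664). None of the 9 tested Fox genes was called by limma. At any fold, 4 of them had an unadjusted p of at most 0.05 and 1, higher in the wild type, an adjusted p of at most 0.05 (camera adjusted p = 0.582, or adjusted p = 0.736 with an estimated correlation; fry adjusted p = 0.0446).

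Wild-type cells expressed the actin-bundling protein fascin (Fscn1), podoplanin (Pdpn), type IV collagen (Col4a1) and the carbonyl reductase Cbr3, which were at or close to 0 FPKM in ΔFOXC2 cells. ΔFOXC2 cells expressed more of the galectin Lgals3, of interferon-stimulated genes such as Oas1a and Isg15, and of the melanosomal transporter Oca2. By limma, 911 genes (8.62% of those tested) were called, 386 higher and 525 lower in the wild type. The groups did not overlap in 3171 of the 10570 tested genes, where chance separates 0.794%. With the unadjusted p, 401 were higher and 531 lower. Without a fold threshold, 2199 were higher and 2193 lower at an adjusted p of at most 0.05, and at 2-fold 148 and 191. For each of the 47 gene lists, the counts of called members adjusted over the list alone equalled those adjusted over all genes.

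**Figure D1:**
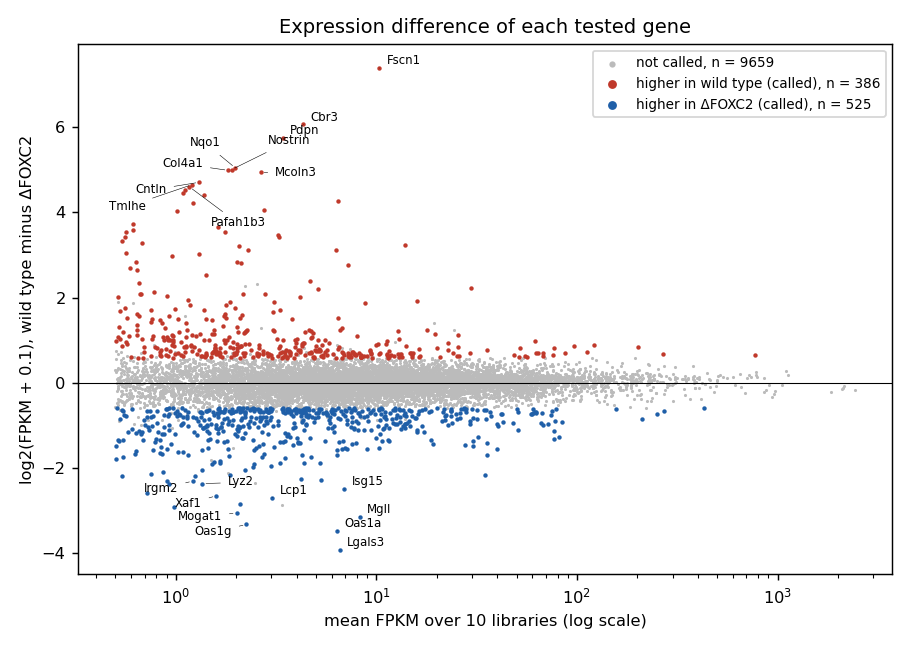
Log2(FPKM + 0.1) difference, wild type minus ΔFOXC2, against mean FPKM over 10 libraries on a log scale; each point is 1 of the 10570 tested genes, red called higher in the wild type (386), blue called higher in ΔFOXC2 (525), grey not called, and the 20 genes named by fold are labelled. The largest differences in the wild type were in genes at or near 0 FPKM in ΔFOXC2 libraries.

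Among the genes with the largest differences, Fscn1 (ENSMUSG00000029581.14, chromosome 5, 142960343 to 142973185) had 20.7 ± 7.45 FPKM in the wild type, with single libraries from 12.3 to 27.6. The 5 ΔFOXC2 libraries had 0, 0, 0.0524, 0.0455 and 0 FPKM (limma adjusted p = 4.713e-09). Its log2 difference was 7.39 with the pseudocount of 0.1, 4.33 with 1 and 9.91 with 0.01, and for genes near 0 in 1 group the pseudocount sets the size of the difference. Cbr3 (chromosome 16, 93683215 to 93690990) had 8.63 ± 1.19 FPKM in the wild type and was listed at 0 in 3 ΔFOXC2 libraries and at 0.0913 and 0.0899 in the others. Pdpn, a surface glycoprotein known from lymphatic endothelium, had 6.80 ± 0.851 FPKM against 0 in 3 libraries and 0.0578 and 0.118 in the others. Nqo1, a quinone reductase and NRF2 target on chromosome 8, had 3.93 ± 0.301 FPKM and was listed at 0 in 4 ΔFOXC2 libraries and at 0.170 in replicate 3. Nostrin, a regulator of nitric oxide synthase trafficking, had 3.78 ± 0.607 FPKM against 0 in 3 ΔFOXC2 libraries and 0.0572 and 0.0557 in the others. The centrosomal gene Cntln had 2.62 ± 0.185 FPKM against 0 in 3 libraries and 0.00724 and 0.0130 in the others. Tmlhe, a carnitine synthesis enzyme, and Pafah1b3, a lipase subunit, had 2.42 ± 0.179 and 2.33 ± 0.201 FPKM in the wild type and were listed at 0 in all 5 ΔFOXC2 libraries. The cation channel Mcoln3 had 5.22 ± 0.448 against 0.0760 ± 0.0374 FPKM (log2 4.94, and 2.53 to 6.05 with the other pseudocounts).

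Lgals3 (galectin-3, ENSMUSG00000050335.17, chromosome 14, 47367751 to 47386160) led the genes named by fold in the other direction, with 0.726 ± 0.111 FPKM in the wild type and 12.4 ± 2.11 in ΔFOXC2 cells (log2 -3.92, SE 0.120, limma adjusted p = 2.248e-09). Mgll, which degrades monoacylglycerols, had 1.87 ± 1.35 against 14.7 ± 1.94 FPKM (log2 -3.14), and Mogat1, which acylates them, 0.387 ± 0.204 against 3.64 ± 0.579 (log2 -3.05). Lcp1, an actin-bundling protein typical of leukocytes, had 0.750 ± 0.255 against 5.31 ± 1.17 FPKM (log2 -2.69), and the lysozyme gene Lyz2 0.386 ± 0.172 against 2.33 ± 0.667 (log2 -2.36). With pseudocounts of 1 and 0.01, the log2 differences were -2.95 and -4.08 for Lgals3, -2.55 and -3.23 for Mgll, -1.75 and -3.39 for Mogat1, -1.84 and -2.84 for Lcp1, and -1.25 and -2.66 for Lyz2.

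Interferon-stimulated genes were mostly lower in the wild type. Of 44 tested, 31 fell, 1 rose and 12 were not called, with a median log2 difference of -1.02 (camera adjusted p = 2.797e-14; adjusted p = 0.449 with an estimated correlation). Isg15, a ubiquitin-like modifier, had 2.03 ± 0.415 against 11.8 ± 2.05 FPKM (log2 -2.49), the apoptosis factor Xaf1 0.361 ± 0.110 against 2.83 ± 0.750 (log2 -2.65), and the GTPase Irgm2 0.355 ± 0.155 against 2.08 ± 0.390 (log2 -2.30). Oas1a (log2 -3.47) and Oas1g (log2 -3.32), neighbouring copies that sense double-stranded RNA, may share reads and their single values are uncertain. The member that rose was Trim25, a ubiquitin ligase of RNA sensing, at 3.31 ± 0.413 against 0.198 ± 0.0609 FPKM (log2 3.53, and 1.84 to 4.04 with pseudocounts of 1 and 0.01). Of 28 receptors and regulators of the interferon pathway, 5 fell and 0 rose (camera adjusted p = 0.454). Among them was the feedback protease Usp18 (log2 -1.53). With pseudocounts of 1 and 0.01, the log2 differences were -1.47 and -2.93 for Xaf1, -1.18 and -2.59 for Irgm2, -2.68 and -3.59 for Oas1a, -1.95 and -3.64 for Oas1g, and -0.92 and -1.65 for Usp18. Of 20 fixed macrophage and leukocyte markers 3 were tested, and Lyz2 and Cd68 (log2 -0.94) fell, with all 3 lower at any fold. The list did not pass with camera (camera adjusted p = 0.0808, or adjusted p = 0.502 with an estimated correlation), while fry called it (fry adjusted p = 4.33e-05).

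**Figure D2:**
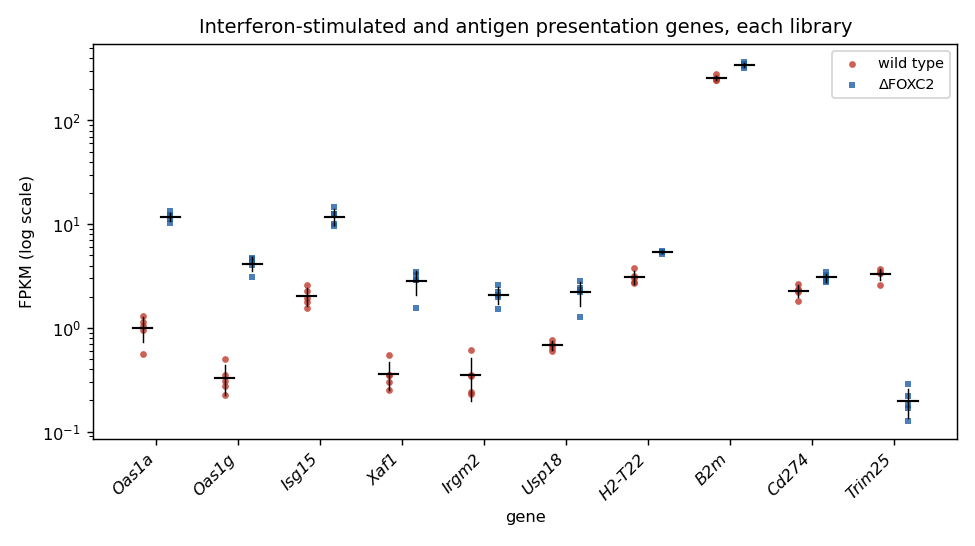
FPKM on a log scale of 10 interferon-stimulated, antigen presentation and checkpoint genes; each point is 1 library, red circles wild type and blue squares ΔFOXC2 (5 each), with horizontal bars at group means and vertical bars of 1 SD. Every gene shown except Trim25 was higher in ΔFOXC2 libraries, and the differences of B2m and Cd274 were under 1.5-fold.

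Of 12 antigen processing and presentation genes, 1 fell and 0 rose, with a median of -0.34 and 9 lower against 1 higher at any fold (camera adjusted p = 0.00153; adjusted p = 0.449 with an estimated correlation). The class I gene H2-T22 fell from 5.36 ± 0.121 FPKM in ΔFOXC2 to 3.10 ± 0.419 in wild-type cells (log2 -0.78), and as one of a family of similar genes its value is uncertain. B2m, the class I light chain, had 257 ± 12.6 against 344 ± 17.3 FPKM (log2 -0.42) and the checkpoint ligand Cd274 (PD-L1) 2.27 ± 0.298 against 3.07 ± 0.264 (log2 -0.42, limma adjusted p = 0.00548), both under 1.5-fold. The chaperone Calr, on chromosome 8, was the exception with a log2 of 0.40, not called. Of 12 checkpoint and natural killer ligands, Cd276 (log2 0.81) and Nectin2 (log2 0.66) rose and 3 fell, including Lgals3 and Lgals9, a galectin at 47.3 ± 3.84 against 115 ± 14.8 FPKM (log2 -1.27), with camera adjusted p = 0.287. Of 12 chemokines and cytokines, Tslp (log2 1.44) and Tgfb2 (log2 1.07, chromosome 1) rose, and Ccl5 (log2 -1.38) and Tgfb1 (log2 -1.38) fell (camera adjusted p = 0.906). Of 12 NF-kB targets 1 rose, Nfkbia (log2 0.59), with camera adjusted p = 0.620. Its fold dropped under the threshold without wild-type replicate 1, 2 or 3 or ΔFOXC2 replicate 4 or 5 (log2 0.54 to 0.57) and with median-of-ratios scaling (log2 0.58).

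Of 25 pigmentation and melanocyte genes, 6 fell, 1 rose and 18 were not called. At any fold 20 were lower and 2 higher, with a median of -0.34 (camera adjusted p = 9.671e-05; adjusted p = 0.697 with an estimated correlation). Oca2, a melanosomal transporter, had 1.74 ± 0.342 against 8.87 ± 1.84 FPKM (log2 -2.28) and the channel Trpm1 2.24 ± 0.783 against 8.19 ± 1.06 (log2 -1.87). The lineage regulator Mitf had 64.3 ± 9.17 against 86.9 ± 9.08 FPKM (log2 -0.44, limma adjusted p = 0.00437), under 1.5-fold, and Mcoln3 was the member that rose. Of 33 lysosomal genes, 4 fell and 1 rose, with 21 lower at any fold and a median of -0.23 (camera adjusted p = 0.000458; adjusted p = 0.653 with an estimated correlation). The proteases Ctsh (log2 -1.66) and Ctsb (48.2 ± 2.99 against 106 ± 7.76 FPKM, log2 -1.14) fell, while the channel Mcoln1 rose (log2 1.18, chromosome 8). Of 30 cholesterol synthesis and uptake genes, 3 fell and 0 rose, Hsd17b7 (log2 -1.40, chromosome 1) and Nsdhl (log2 -0.65) among them (camera adjusted p = 0.0392; adjusted p = 0.736 with an estimated correlation). The list did not pass without wild-type replicate 4 (camera adjusted p = 0.0550) or 5 (0.0987) or without ΔFOXC2 replicate 3 (0.0927). It also failed with a filter at 5 FPKM (0.0546) or with the replicate number as a block (0.0691).

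Matrix and mesenchymal genes went both ways. Of 15 matrix and basement membrane genes, 5 rose and 2 fell, and of 11 mesenchymal genes 1 rose and 4 fell (camera adjusted p = 0.952 and 0.700). Col4a1, on chromosome 8, had 3.64 ± 0.739 FPKM in the wild type and 0 in 2 ΔFOXC2 libraries, with 0.0145, 0.0423 and 0.0301 in the others. Its neighbour Col4a2 had 1.78 ± 0.209 against 0.140 ± 0.0246 (log2 2.97, and 1.28 to 3.59 with pseudocounts of 1 and 0.01). Thbs1, a matrix glycoprotein, rose (log2 0.71). Sparc, which binds collagen, had 150 ± 7.45 against 271 ± 14.8 FPKM and fell (log2 -0.85). The secreted factor Ctgf had 5.96 ± 0.436 against 15.4 ± 0.968 FPKM (log2 -1.35) and the transcription factor Snai2 7.91 ± 1.05 against 13.2 ± 1.53 (log2 -0.73), and both fell. Fibronectin (Fn1, chromosome 1) fell (log2 -0.66), and its fold was under the threshold without ΔFOXC2 replicate 1 (log2 -0.56). Vim had 299 ± 16.5 against 302 ± 17.4 FPKM (limma adjusted p = 0.812) and Cdh2 a log2 of 0.27. Of 9 integrins 1 fell, Itgb3, at 1.17 ± 0.164 against 4.77 ± 0.424 FPKM (log2 -1.94), and Itgb1, on chromosome 8, had a log2 of 0.30 (camera adjusted p = 0.686).

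Of 20 matrix proteases and inhibitors, 2 rose and 3 fell (camera adjusted p = 0.906). The serine protease inhibitor Serpine2 (chromosome 1) had 1.18 ± 0.354 against 0.0803 ± 0.0462 FPKM (log2 2.83, and 1.00 to 3.84 with pseudocounts of 1 and 0.01), the protease Adam9 (chromosome 8) 140 ± 4.15 against 84.7 ± 4.57 (log2 0.73), and the plasminogen activator Plat (chromosome 8) fell (log2 -1.14). Of 12 angiogenesis genes 3 rose and 3 fell (camera adjusted p = 0.718): the lymphatic growth factor Vegfc (chromosome 8) rose (log2 1.00), and Angpt2 (log2 -0.87, chromosome 8) and Sema3c (log2 -1.34) fell. Of 24 melanoma metastasis and invasion genes 3 rose, Fscn1 and Bcan (log2 1.67) among them, and 1 fell, Lgals3 (camera adjusted p = 0.906).

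In drug handling, Abcc2, an efflux pump, had 0.620 ± 0.0851 against 3.10 ± 0.303 FPKM (log2 -2.15). Of 21 efflux transporters 3 fell, Abca5 (log2 -0.76) among them, and 1 rose, Slc22a18 (log2 1.07), with camera adjusted p = 0.171. Of 34 genes of drug and xenobiotic metabolism, 4 rose and 6 fell (camera adjusted p = 0.161). Besides Cbr3 and Nqo1, the epoxide hydrolase Ephx1 (chromosome 1) had 44.9 ± 2.17 against 89.8 ± 9.97 FPKM (log2 -0.99), and Cda, which inactivates cytidine drugs, fell (log2 -1.18). Of 24 NRF2 antioxidant genes, Nqo1 and Slc7a11 (log2 0.93) rose, and Srxn1 (log2 -0.90, distal chromosome 2) and Blvrb (log2 -0.96) fell, with camera adjusted p = 0.646. The call of Slc7a11 was lost without ΔFOXC2 replicate 1 (adjusted p = 0.0559) or 5 (0.0576).

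Of 44 cell cycle genes none was called by limma. At any fold 14 were higher and 2 lower, 19 had an unadjusted p of at most 0.05, and the median was 0.09 (camera adjusted p = 0.0677, or adjusted p = 0.736 with an estimated correlation; fry called the list, at 0.0276). Without wild-type replicate 5 or ΔFOXC2 replicate 2 the list passed (camera adjusted p = 0.0125 and 0.0128), as it did with chromosomes 1, 8 and distal 2 left out (0.0141) or centred (0.00567). Mki67 had 116 ± 10.9 against 99.6 ± 8.64 FPKM (log2 0.22) and Pcna 189 ± 9.76 against 163 ± 11 (log2 0.21). Of 15 cyclin-dependent kinase inhibitors and G1 regulators 2 fell, Ccnd1, 45.3 ± 2.45 against 87.5 ± 12 FPKM (log2 -0.94), and Cdkn1a, 53.9 ± 3.56 against 101 ± 11.8 (log2 -0.90), with camera adjusted p = 0.385. Of 22 p53 targets 2 rose and 4 fell (camera adjusted p = 0.0808), with Btg2 (log2 -1.50) and Phlda3 (log2 -1.11), both on chromosome 1, the largest. Bbc3 rose (log2 0.66), and its call was lost without wild-type replicate 2 or 5 or ΔFOXC2 replicate 1, 4 or 5 (log2 0.53 to 0.65, adjusted p = 0.0517 to 0.0657). Of 27 apoptosis regulators 3 rose, Casp2 (log2 0.75) among them. Another 2 fell, the inhibitors Bcl2 (log2 -0.77) and Cflar (log2 -0.99), both on chromosome 1 (camera adjusted p = 0.608).

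Of 31 genes of the unfolded protein and integrated stress responses, 7 rose and 1, Aldh1l2 (log2 -0.89), fell (camera adjusted p = 0.507). Herpud1 (chromosome 8), of endoplasmic reticulum degradation, had 34.7 ± 5.91 against 16.4 ± 6.00 FPKM (log2 1.13), and the glutathione-degrading Chac1 23.6 ± 6.96 against 12.1 ± 8.35 (log2 1.23, adjusted p = 0.0494). The Chac1 call was lost without wild-type replicate 2, 3, 4 or 5 or ΔFOXC2 replicate 1, 4 or 5 (log2 0.88 to 1.31, adjusted p = 0.0640 to 0.113). It was also lost with median-of-ratios scaling (0.0509), robust variances (0.0744) or no variance trend (0.0630), and with chromosomes 1, 8 and distal 2 left out (0.0539) or centred (0.0545). Of 21 hypoxia targets 5 rose and 0 fell, Ankrd37 (log2 1.09, chromosome 8) and Adm (log2 0.76) among them (camera adjusted p = 0.171), and of 16 heat shock genes 1 fell, Hspb1 (log2 -0.87), with camera adjusted p = 0.502. No gene of glycolysis (21 tested) or oxidative phosphorylation (45 tested) was called by limma. At any fold, 6 and 13 were higher and 3 and 5 lower, and 9 and 23 had an unadjusted p of at most 0.05 (camera adjusted p = 0.700 and 0.415). Gapdh (log2 0.08, limma adjusted p = 0.617) and Actb (log2 -0.02, limma adjusted p = 0.797) differed by less than the spread. No cytosolic ribosomal protein gene was called by limma among 45. At any fold, 29 were higher and 0 lower and 32 had an unadjusted p of at most 0.05, with a median of 0.13 (camera adjusted p = 9.671e-05; adjusted p = 0.736 with an estimated correlation). Rpl8 (log2 0.11) and Rpl19 (log2 0.13) were the most abundant.

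**Figure D3:**
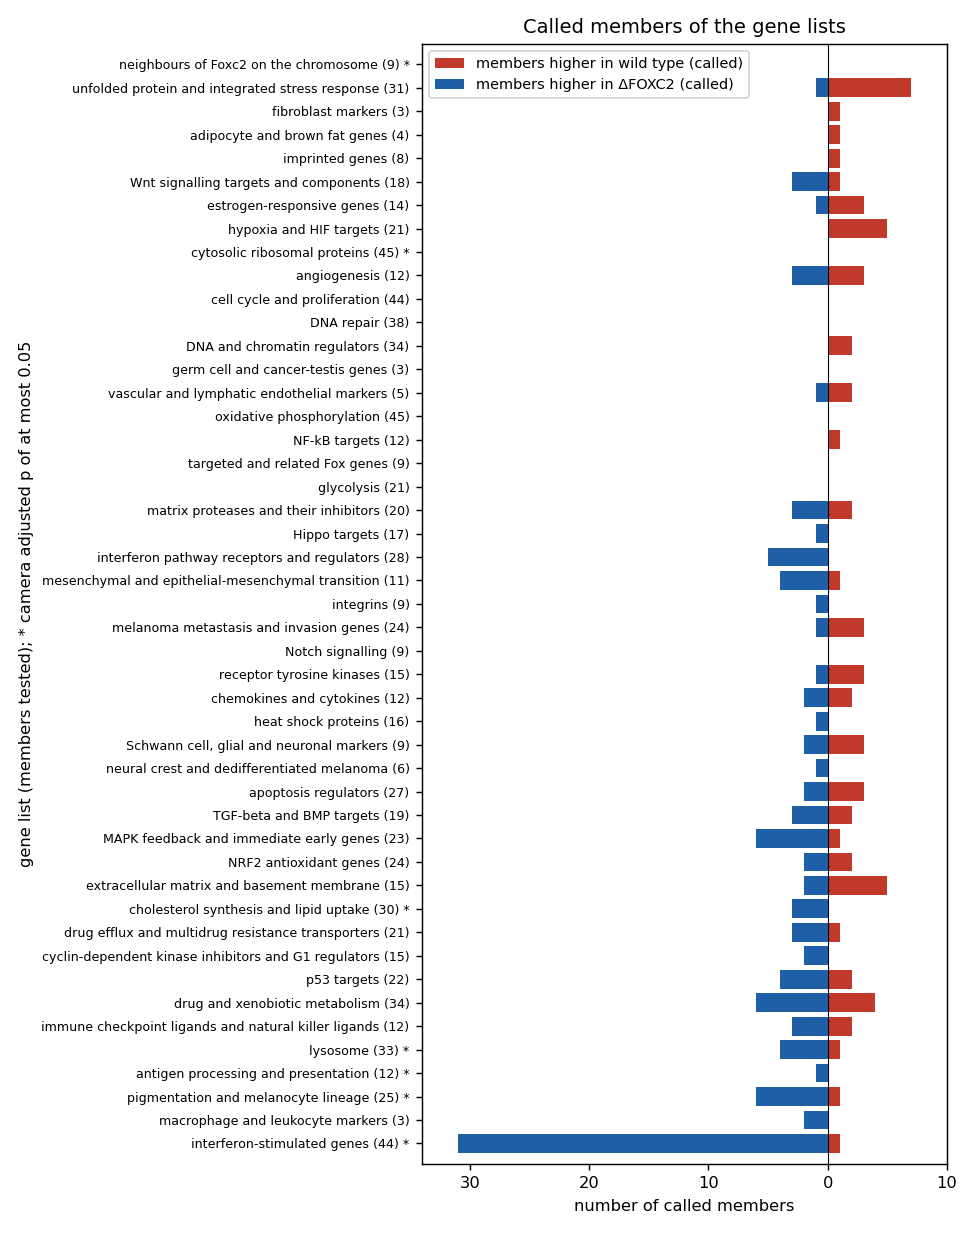
Number of called members of each of 47 gene lists, red to the right for members higher in the wild type and blue to the left for members higher in ΔFOXC2, ordered by median log2 difference with the highest at the top; numbers in brackets are tested members, and asterisks mark lists with a camera adjusted p of at most 0.05. The interferon-stimulated list had the most called members, 31 lower and 1 higher in the wild type.

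Genes were shifted together along chromosomes 8 and 1. The 9 tested neighbours of Foxc2 on chromosome 8 had a median of 0.44, none called by limma, and 7 higher at any fold by adjusted as by unadjusted p (camera adjusted p = 0.00131; adjusted p = 0.449 with an estimated correlation). Of these, Cox4i1 had 104 ± 6.13 against 76.4 ± 3.13 FPKM (log2 0.44) and Map1lc3b a log2 of 0.54. The fold of Map1lc3b passed the threshold without ΔFOXC2 replicate 1 (log2 0.62) or 4 (log2 0.61). Over all 578 tested genes of chromosome 8 the median was 0.36 (bootstrap interval 0.34 to 0.38) and 89.6% were above 0. There, 92 rose and 4 fell, which is 23.8% of all genes called higher from 5.47% of the genes. Bootstrap intervals resample genes, not libraries, and do not measure the spread between cultures. Over the 573 genes of chromosome 1 the median was -0.26, 11.2% were above 0, and 7 rose and 77 fell. The 254 genes of chromosome 2 from 150 Mb on had a median of -0.26. In bins of 10 Mb the medians there were -0.32, -0.23 and -0.32, and 0.08 for the 34 genes from 180 Mb on, which were left out or centred with the rest of the region. The 9165 genes outside these 3 regions had a median of 0.01. Smaller shifts were seen on chromosome 14, with a median of -0.13 (bootstrap interval -0.16 to -0.11), 23.3% of genes above 0, 6 risen and 34 fallen, and on chromosome 10, with a median of -0.11 (-0.13 to -0.08), 31.4% above 0, 9 risen and 41 fallen. All 13 bins of 10 Mb on chromosome 10 and 11 of 13 on chromosome 14 had a median below 0. Chromosome 8 held 5.03% ± 0.0346 of the FPKM sum in the wild type and 3.92% ± 0.0434 in ΔFOXC2 cells. Chromosome 1 held 4.79% ± 0.0449 and 5.64% ± 0.0324 (SD, n = 5 each). With the median of each region subtracted, the neighbours list did not pass (camera adjusted p = 0.647). The calls of Adam9 (log2 0.36), Plvap (log2 0.50), Bcl2 (log2 -0.51), Fn1 (log2 -0.40) and Ankrd37 (log2 0.73, adjusted p = 0.0971) were lost, and Itgb1 reversed (-0.068).

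**Figure D4:**
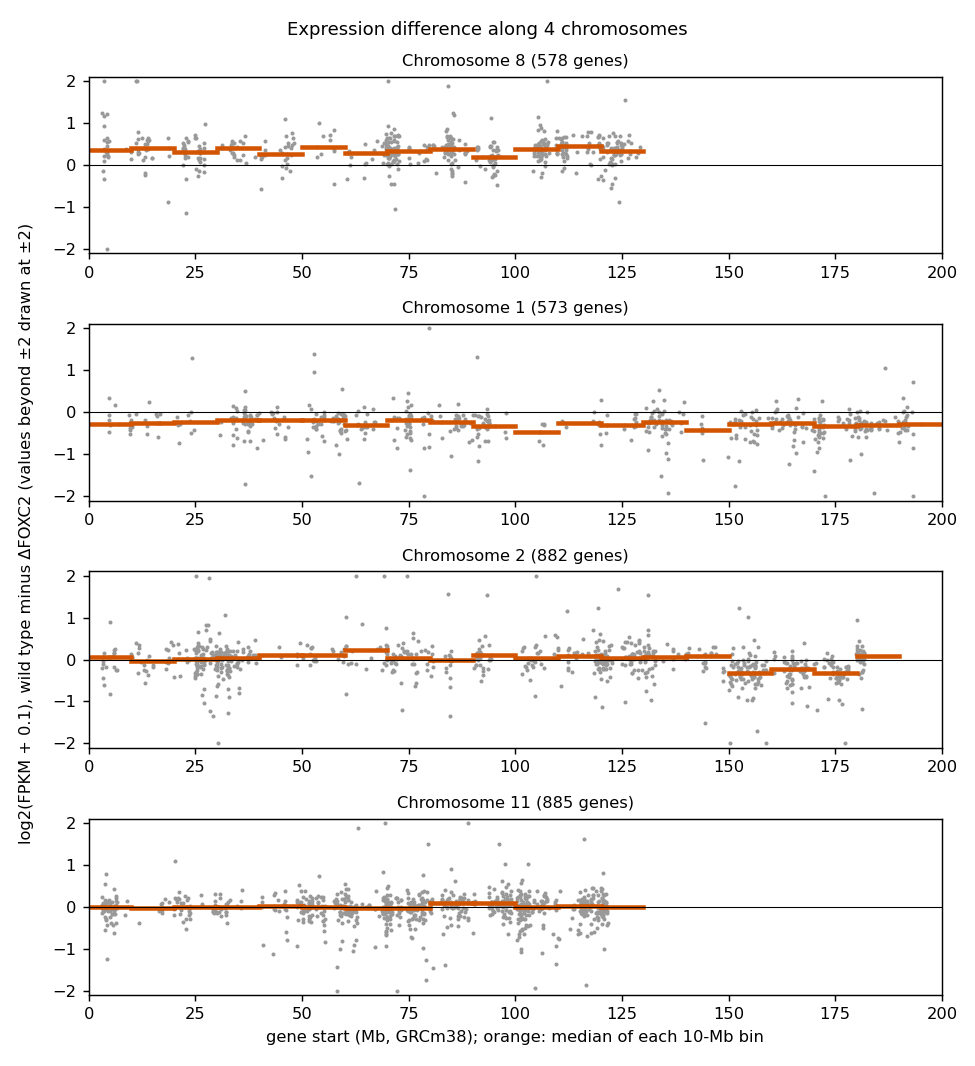
Log2(FPKM + 0.1) difference, wild type minus ΔFOXC2, of each tested gene (grey) against its start in Mb along chromosomes 8, 1, 2 and, for comparison, 11, with orange lines at the median of each 10-Mb bin; values beyond 2 in size are drawn at the edge. All 13 bins of chromosome 8 lay above 0 (0.20 to 0.46) and all 20 of chromosome 1 below 0 (-0.47 to -0.18).

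Over the 47 lists, 7 passed with camera, 2 higher and 5 lower in the wild type, and 0 with an estimated correlation, where 4 had an unadjusted p of at most 0.05; fry called 33. The median, the mean and the test differed in sign for 9 lists, none past the camera threshold: matrix and basement membrane, matrix proteases, drug metabolism, NRF2 targets, apoptosis, Notch signalling, glial markers, receptor tyrosine kinases and metastasis genes. With a filter at 5 FPKM, 4 further lists passed, each lower in the wild type: matrix and basement membrane (camera adjusted p = 0.00269), checkpoint ligands (0.0185), drug metabolism (0.0182) and p53 targets (0.0182). An estimated correlation was not run with that filter. With a pseudocount of 1, the folds of Cd276, Slc22a18, Bbc3, Adm, Ankrd37, Nfkbia, Thbs1, Tet1, Sirt1 and Ppargc1a (log2 0.39 to 0.56), Cd68 (log2 -0.51) and Abca5 (log2 -0.41) were under 1.5. With pseudocounts of 1 and 0.01, the log2 differences were -1.34 and -2.31 for Abcc2, -0.79 and -1.90 for Ctsh, and 0.65 and 1.67 for Tslp.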

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

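Which libraries stand apart was judged by the gap of the highest or lowest library to the nearest of its group, set against the range of the group, for 117 named genes and the FPKM sum. Of 236 groups of 5 libraries, 21 stood out, where chance gives about 1 in 20. The values below are FPKM unless stated.

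Among wild-type libraries, replicate 1 had the highest FPKM sum, 251273 against at most 242895 in the others, and stood apart for B2m (278), Actb (502) and Epha3 (20.9, the lowest). Replicate 2 stood apart for Lgals3 (0.916), Foxc1 (5.77, the lowest) and Pcdhga4 (3.87), replicate 3 for Slc22a18 (1.55), replicate 4 for Srxn1 (17.9, the lowest) and Pet117 (0.0046), and replicate 5 for Tcf7l1 (12, the lowest). Among ΔFOXC2 libraries, replicate 3 stood apart for Nqo1 (0.170, with the other 4 at 0), Ctsh (0.692, the lowest), Bcan (1.06, the lowest), Egfl7 (2.41, the lowest) and Pet117 (19.2, with at most 0.0047 in the others). Replicate 2 stood apart for Lgals3 (16.1), replicate 4 for Egr1 (6.13) and Tet1 (0.198, the lowest), replicate 1 for Rragb (0.0473) and replicate 5 for Pcdhgc3 (0.350). Rragb, Pcdhga4, Pcdhgc3 and Pet117 were named after their values were seen.

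Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many called genes as the real 911. The highest of the others gave 5. Every other split mixes libraries of both lines in each group, so the difference between the lines adds to the spread within groups and lowers the calls. The counts therefore show that the calls follow the grouping by line. They cannot tell how many genes would be called by chance between groups of like libraries.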

How the results depend on the processing

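Chromosome 1, chromosome 8 and distal chromosome 2 were left out or centred only after the data had been seen. With 1 library left out, 370 to 409 genes were higher and 505 to 554 lower in the wild type, 383 to 424 and 520 to 566 with the unadjusted p, and 1942 to 2209 and 1970 to 2192 at any fold. Between 6 and 8 lists passed. Of the 911 genes, 830 to 870 were also called in each of these fits, and none was called in the opposite direction under any alternative run. A pseudocount of 1 left 230 higher and 338 lower (234 and 340 unadjusted), since it shrinks the fold of low genes. A filter at 5 FPKM left 123 and 217 (127 and 218 unadjusted), because 571 of the 911 genes were no longer tested. A fold of 2 left 148 and 191 (151 and 191 unadjusted), and an adjusted p of at most 0.01 left 1402 genes higher and 1509 lower at any fold. The other settings that kept all genes gave 314 to 441 higher and 488 to 567 lower. Without the 3 regions, 283 were higher and 420 lower, and 703 of the 911 were kept with 205 not tested; with region centring 314 and 488 were called, 772 of them among the 911. With an estimated correlation 0 lists passed and with fry 33. Over the 117 named genes and the alternatives, 2602 values kept their direction and side of the threshold, 96 lost the call, 5 gained it and 10 changed sign. Over the lists, 1165 kept their side of the threshold, 14 lost the call, 36 gained it and 0 were called the other way. Changes in the sign of a list median were not counted. The sign changed for genes with no call: Itgb1 with region centring (-0.068), Actb (-0.076 to 0.0053 with 1 library left out), Vim (-0.048 to 0.0091) and Eif3j2 (-1.25 to 1.17); the cause was not tested. The labels do not say that libraries with the same number share a day or culture. Their deviations correlated at -0.121 to 0.137, and 5 of 10 libraries matched their own number best where chance gives 2. The matches were sought in both directions over the same correlations, so they are not independent. The count was not tested, and pairing is left open. With the replicate number as a block, 390 genes were higher and 526 lower, 901 of the 911 were kept, and the cholesterol list no longer passed (camera adjusted p = 0.0691). Depth is unknown, so how firmly genes near 0 FPKM can be told from 0 is not known.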

Other observations

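The test of leukocytes was chosen only after the result was seen, as was the choice of chromosomes.

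Of 9 Schwann cell, glial and neuronal markers, 3 rose and 2 fell in the wild type (camera adjusted p = 0.860). The myelin gene Mbp had 12.3 ± 0.973 against 0.572 ± 0.218 FPKM (log2 4.27) and Pmp22 13.8 ± 0.885 against 3.72 ± 0.534 (log2 1.88) and rose, while S100b (log2 -0.76) fell. Of 6 neural crest genes 1 fell, Snai2 (camera adjusted p = 0.646). Of 15 receptor tyrosine kinases 3 rose and 1 fell (camera adjusted p = 0.700). Epha3 had 25.3 ± 2.56 against 6.69 ± 1.32 FPKM (log2 1.92), the insulin receptor Insr (chromosome 8) a log2 of 1.23, and Met 20.5 ± 8.31 against 51.1 ± 6.24 FPKM (log2 -1.42). Endothelial markers went both ways, with Pdpn and Plvap (log2 0.86, chromosome 8) up and Egfl7 (log2 -0.85) down among 5 (camera adjusted p = 0.700). Of 3 fibroblast markers Pdpn alone rose (camera adjusted p = 0.536), and of 4 adipocyte genes Ppargc1a (log2 0.66), whose fold was under the threshold without wild-type replicate 5 (log2 0.53), with camera adjusted p = 0.813. Of 8 imprinted genes 1 rose, Ppp1r9a (log2 1.90, camera adjusted p = 0.454). None of 3 germ cell genes was called by limma, with 0 at an adjusted or unadjusted p of at most 0.05 at any fold (camera adjusted p = 0.718). Of the lists with too few tested genes, epithelial genes had 1 of 20 and erythroid and Y-linked genes 0.

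In signalling, 6 of 23 MAPK feedback and immediate early genes fell and 1 rose (camera adjusted p = 0.259): Egr1 (log2 -2.04) and the phosphatase Dusp10 (log2 -1.91, chromosome 1) fell, and Spry1 (log2 0.94) rose. Of 18 Wnt genes 3 fell, Ccnd1 and Dkk3 (log2 -0.72) among them, and Tcf7l1 (log2 0.74) rose (camera adjusted p = 0.582). Of 19 TGF-beta and BMP targets 2 rose, Atoh8 (log2 1.48) among them, and 3 fell, Id3 (log2 -0.96) among them (camera adjusted p = 0.588). Of 17 Hippo targets 1 fell, Ctgf (camera adjusted p = 0.588), and of 9 Notch genes none was called by limma (camera adjusted p = 0.700), with 2 higher at any fold by adjusted as by unadjusted p. Of 14 estrogen-responsive genes 3 rose, Olfm1 (log2 1.94) the most, and Ccnd1 fell (camera adjusted p = 0.263). Of 34 chromatin regulators 2 rose, Tet1 (log2 0.99) and Sirt1 (log2 0.71), with camera adjusted p = 0.175. Of 38 DNA repair genes none was called by limma, with 8 higher and 5 lower at any fold and 16 at an unadjusted p of at most 0.05 (camera adjusted p = 0.507, or adjusted p = 0.736 with an estimated correlation; fry adjusted p = 0.0307). With chromosomes 1, 8 and distal 2 centred, the MAPK (camera adjusted p = 0.0261) and chromatin lists (0.0425) passed. Without centring, their adjusted p was 0.804 and 0.736 with an estimated correlation. With pseudocounts of 1 and 0.01, the log2 differences were 3.09 and 4.50 for Mbp, -1.34 and -2.16 for Egr1, -1.12 and -2.07 for Dusp10, 0.70 and 1.69 for Atoh8, 1.02 and 2.16 for Olfm1, and 1.21 and 2.03 for Ppp1r9a.

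Chromosome 8 was higher and chromosome 1 lower in the wild type throughout their length. After correction for GC content, transcript length and expression level, the median of chromosome 8 still lay 0.347 (0.322 to 0.368) above that of the other genes. That of chromosome 1 lay -0.265 (-0.285 to -0.246) from it. The 2 values argue against those measures as the whole source. Their intervals resample genes and do not measure the spread between cultures. The spread of log2 differences on chromosome 8 was 1.02 times that of the rest. An even shift of any origin gives such a ratio, as does no shift, so the ratio cannot single out a difference in copies. That the 2 lines may differ in copies of chromosome 8 is a hypothesis. The spread was not tested for chromosome 1, where fewer copies in the wild type stay open. Whether FOXC2 or the derivation of the line came first stays open, and no copy number was measured.

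Interferon-stimulated genes were mostly lower in the wild type, or higher in ΔFOXC2 cells. The median over the 40 members outside chromosomes 1, 8 and distal 2 was -1.05 (-1.54 to -0.71). After correction for GC content, length and expression the median of the list was -0.988 (-1.50 to -0.613). The 2 medians argue against either as the whole source. Their intervals resample genes, which are correlated here, and not libraries. Leukocytes among the ΔFOXC2 cells could also carry such genes, although all libraries are labelled as B16-F1 cells. This source cannot be told apart here, because 3 of 20 fixed leukocyte markers were tested, too few to decide. All 3 were lower in the wild type at any fold, and 2 of them, Lyz2 and Cd68, were called. Cd68 is also a member of the lysosomal list, where 21 of 33 were lower at any fold. Loss of FOXC2 itself stays open as untested.

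Genes that were near 0 in 1 group (mean under 0.1 FPKM) and at 1 FPKM or more in the other were mostly near 0 in ΔFOXC2 cells: 27 there, 24 with groups apart and 6 listed at 0 in all 5 libraries, against 1 in the wild type, Pet117, which rests on 1 ΔFOXC2 library at 19.2 FPKM. Of the 28, 25 were called, of which Pcdhgc3 was not called without wild-type replicate 2, 3 or 5 or ΔFOXC2 replicate 1, 2, 3 or 4 (adjusted p = 0.0618 to 0.0797), with quantile normalization (0.0896) or with robust variances (0.0529). As to deletions that span several genes, 4 of 28 had another such gene within 1 Mb. These were Mageh1 with Rragb on chromosome X and Pcdhgc3 with Pcdhga4 on chromosome 18, the latter pair overlapping genes of 1 cluster. Most of the 28 thus had no such neighbour, but the number expected by chance was not computed. Deletions stay open, because the limits pass over partial falls and some genes had few neighbours. Col4a2, beside Col4a1, had 0.140 ± 0.0246 FPKM in ΔFOXC2 cells, and Cntln had 1 gene of the table within 1 Mb. Reads moved to an overlapping gene of the table on the same strand are argued against for most, since 4 of 28 overlapped one. Genes outside the table and similar copies elsewhere were not covered, so reads moved to those stay open. Silencing or loss of single genes during derivation of the line, and loss of FOXC2, stay open as hypotheses; a split of the cells through a small number of founders could give the same, and no test here separates them.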
